A study of Mus musculus with 24 samples.

How the data were processed

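DNA methylation was measured by reduced representation bisulfite sequencing (RRBS) of sperm genomic DNA from 24 male mice. In this assay, DNA is digested with MspI, which opens CCGG sites, and short fragments are kept, so that CpG-rich parts of the genome are read deeply. Unmethylated cytosines are then read as T and methylated ones as C. Per the submitters' processing notes, Trim Galore 0.3.3, BSMAP 2.6 and build mm10 were used; their settings, the methylation caller and the treatment of duplicate reads were not stated.

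Each of the 24 deposited tables covers 1 male and lists cytosines of CpGs on both strands. Per the file headers and the values, the deposited coverage is a raw read count with a ceiling of 65535 reads and no minimum. The deposited methylation values are the percent of reads with C and with T, given to 1 decimal. The product of percent and coverage was a whole number of reads at 99.7 to 99.9% of positions, within a tolerance of 0.0006 reads per read of coverage, and methylated reads were recovered as this product rounded to the nearest whole number. Reads are not marked by molecule, so counts include copies made by PCR.

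Both strands of a CpG were added, and chromosomes 1 to 19, X and Y were kept. Of 2995280 CpGs read in any male, 2260042 had a read in every male. CpGs were joined into fixed tiles of 100 bp. A tile entered the means if it held at least 2 CpGs and 10 reads in every male, which left 468726 tiles. A tile was tested if its mean level over all males also lay between 2 and 98%, which left 308594 tiles with a median coverage of 144.5 reads per male. A level is the percent of methylated reads in the tile, differences are in percentage points, and ± gives the SD over the 6 males of a group.

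Tiles were compared with a quasi-binomial logistic regression that holds 1 mean for each of the 4 groups. Per-tile Pearson dispersions, with 20 residual degrees of freedom, were squeezed toward a common prior of 1.86 by empirical Bayes, with 14.9 prior degrees of freedom, as in limma, and floored at 1. F tests were adjusted by the Benjamini-Hochberg method over all tested tiles of a comparison. A tile was called lower or higher at an adjusted p under 0.05 and a difference of group means of at least 10 points. The 5 pairwise comparisons and the interaction (the genotype difference on the high-fat diet minus that on the control diet) came from this fit. Mean levels over tiles, over genome classes and over gene lists were compared with two-sided exact permutation tests over all 924 relabelings of 12 males, of which the smallest possible p is 0.00216. Interactions of these means were tested by exact permutation of the diets within each genotype. Adjusted values are Benjamini-Hochberg values over the 14 lists or 19 classes of a comparison, or over the 5 comparisons for the mean over tiles. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) was the alternative tool, and figures were drawn with matplotlib 3.10.9.

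Genes came from a RefSeq gene table of the same mouse assembly, GRCm38, which gives the start and end of 34614 genes without strand or exons. The transcription start was therefore replaced by the gene end with more CpGs nearby, which could be named for 24123 genes and is called the CpG-dense end here. This departs from the design, which had asked for transcription starts. Tiles within 1 kb of a gene end, in a gene body or outside genes formed the classes. Exons, introns and repeats were not analysed here for lack of an annotation.

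The comparisons, tests, thresholds, gene lists and the rule for named genes were set before the data were examined. By that rule, the named genes are those of up to 12 lower and 12 higher called tiles with the largest differences for comparisons against WT males on the control diet, and up to 5 and 5 for the others, with 1 tile per gene in a gene or within 1 kb of it and unnamed gene models left out. Members of the lists with a called tile near their CpG-dense end are named as well, with up to 4 each for the receptor, zinc finger, protocadherin and Hox families, as are the imprinted regions and Dnmt3l. Genes named outside this rule are marked as chosen after their values were seen. The 14 lists were imprinted regions methylated in sperm, imprinted regions methylated in oocytes, germ-cell genes, DNA methylation and piRNA genes, placental genes, metabolic genes, pluripotency genes, embryo patterning genes, Hox genes, clustered protocadherins, olfactory and vomeronasal receptors, zinc finger genes, and markers of epididymal epithelium and of leukocytes. Paternally methylated regions were searched in windows upstream of Zdbf2, Rasgrf1, Meg3 and H19, and the tiles in these windows form that list here. The windows were counted from the gene ends in the gene table, for Zdbf2 from 63200358. Whether the tiles lie within the imprinted regions themselves was not tested. Nespas and Dnmt3c, a member each of the oocyte list and the methylation list, were not in the gene table.

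The pipeline was tested on simulated data. Reads were redrawn for 308594 tiles at the deposited coverage, with 200 tiles changed by 10 to 30 points in a comparison. All changes were losses, at tiles drawn from intermediate to high mean levels. Gains, and changes at tiles of the lowest and highest levels, were not simulated. For Het against WT on the control diet 134 of the 200 were called with 5 unchanged tiles, for diet in WT males 120 with 4, and for diet in Het males 136 with 2. In WT males, 20% of the diet changes of 10 points were called, 50% of those of 15, 74% of those of 20 and 96% of those of 30. On a subset of 20000 tiles edgeR called 135 of 200 changed tiles and 0 unchanged ones, of which 4.39% had an unadjusted p under 0.05, and the quasi-binomial test called 156 with 5. Alternatives that were tried include the coverage minimum, single CpGs in place of tiles, a logistic test without overdispersion, edgeR, the difference threshold, the number of CpGs per tile, a fit of only the groups compared, the chromosome of Dnmt3l left out, the filters on level and on very high coverage, and each male left out in turn.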

Results

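Sperm DNA methylation was measured by RRBS in 24 male mice of 4 groups of 6. The males were wild-type (WT) or heterozygous for Dnmt3L (Het). Each genotype received a diet with 60% of kcal as fat (the high-fat diet, HFD) or one with 10% (the matched control diet, MCD), and both diets held 2 mg of folate per kg. Feeding began at 8 weeks of age and lasted 11 to 13 weeks, and sperm came from the cauda epididymis by swim-out. Dnmt3L is a cofactor of the enzymes that lay down new DNA methylation in germ cells. The study asks how loss of 1 copy of Dnmt3L and a high-fat diet, alone or together, affect methylation of sperm DNA.

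Total coverage adds the reads at all listed cytosines, so a read that covers several cytosines is counted several times. Values per M reads and shares of all reads below refer to this total. It ranged from 112 to 169 M in WT males on MCD and from 127 to 188 M in WT males on HFD. It ranged from 137 to 157 M in Het males on MCD and from 145 to 204 M in Het males on HFD. Het males on HFD had 20.3 M more than Het males on MCD (exact permutation p = 0.0411). Het minus WT was 0.497 M on MCD (exact p = 0.972) and 3.93 M on HFD (exact p = 0.751). Median coverage of a tile was 97 to 209 reads per library. Replicates of a group correlated with r between 0.979 and 0.987 across tiles, which are not independent replicates. Their tile levels varied more than read counting alone gives, with a chi-square per tile of 1.88 to 3.08 between pairs.

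At the Dnmt3l gene itself (mm10, chromosome 10, 78042287 to 78063622), 80 CpGs in and around the gene were read at 0.975 times the WT coverage in Het libraries, as a share of all reads (exact p = 0.413). The labels do not say which part of the gene the allele lacks, so this coverage does not bear on the genotype. Methylation over the 80 CpGs was 16.2% ± 1.41 (SD, n = 12) in Het and 17.5% ± 1.96 in WT males, a difference of -1.25 points (exact p = 0.0931). Of 7 windows of 1 kb, the one from 78042001 had 33.6% ± 2.44 against 39.3% ± 3.67 over 11 CpGs (exact p = 9.14e-05). The one from 78049001 was higher in Het males, 2.04% against 0.683% over 10 CpGs (exact p = 0.00257), and the other 5 had exact p of 0.0542 to 0.902.

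Het sperm on MCD had lost methylation at 11944 tiles and gained it at 80, relative to WT sperm on the same diet. This comparison addresses Dnmt3L haploinsufficiency on the control diet. A separate breeding line of the Het males cannot be told apart from the genotype here, as the reads on chromosome Y given below show. The called tiles had a median difference of -13.8 points, within a range of -53.3 to 27.9, and 99.3% of them were lower in Het males. Lower tiles lay in 1989 genes, 1363 of them protein-coding, and formed 7568 regions when tiles up to 1 kb apart were joined, 189 of which held 5 tiles or more. The mean level over all tiles was 55.4% ± 0.182 in Het and 56.5% ± 0.0893 in WT males, a difference of -1.17 points (exact p = 0.00216, adjusted p = 0.00361) with all 6 Het males below every WT male. Weighted by each library's own coverage, so that the deepest tiles dominate, the difference was 0.933 points (exact p = 0.468), and with the same coverage weights in every library it was -0.822 (exact p = 0.00216).

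**Figure D1:**
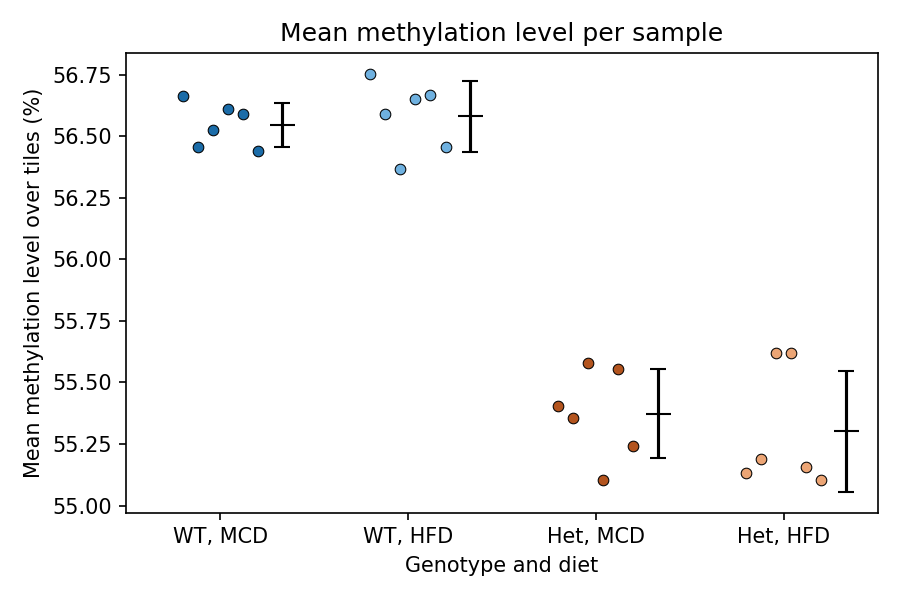
Mean methylation level over 468726 tiles in percent (y axis, not starting at 0) for the 4 groups of genotype and diet (x axis). Each point is 1 male, and the bars give the group mean and SD (n = 6); the 12 Het males lie between 55.1 and 55.6% and the 12 WT males between 56.4 and 56.8%.

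Among tiles in or near named genes, the largest losses on MCD were these. Iqschfp (chromosome 3, 68525201 to 68525300, 5 CpGs, median coverage 149.5 reads) had 32.2% ± 10.6 in Het and 79.4% ± 12.5 in WT males, a difference of -47.1 points (adjusted p = 5.83e-06, lower in 6 of 6 Het males). Ank3, which encodes the scaffold ankyrin-G of axons and membranes, had 48.5% ± 7.32 against 88.8% ± 5.20 at chromosome 10, 69605401 to 69605500 (2 CpGs, coverage 146 reads, adjusted p = 3.57e-09, 6 of 6). Cntn6, a neuronal adhesion molecule, had -40.4 points, Auts2, a regulator of brain development, -34.1, and Adgrv1, an adhesion receptor of hair cells, -33.9. Cfap53 of motile cilia had 24.2% ± 7.25 against 61.9% ± 6.29 (-37.7 points, chromosome 18, 74295101 to 74295200, coverage 516 reads). The tubulin-modifying enzyme gene Ttll7 had -37.4 points and the sperm membrane protein gene Adam3 -32.9. The RNA demethylase gene Fto, whose human variants go with body weight, had 28.1% ± 8.69 against 65.3% ± 6.71 (-37.2 points, chromosome 8, 91436001 to 91436100, 5 CpGs, coverage 228 reads, adjusted p = 1.27e-06). The lectin gene Itln1 had -36.1 points near its CpG-dense end, the myosin light chain gene Myl10 -35.5 and the tight-junction gene Cldn10 -34.9. All 12 tiles were below the WT mean in 6 of 6 Het males, with a largest adjusted p of 0.00790. In 10 of the 12, no Het male reached any WT male.

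Gains on MCD were fewer, and the 12 named genes with the largest ones gained between 15.8 and 24.3 points, with at least 5 of 6 Het males above the WT mean and adjusted p up to 0.0320. Ptprm, a receptor tyrosine phosphatase, had 39.9% ± 15.5 in Het and 15.6% ± 4.21 in WT males (chromosome 17, 67084201 to 67084300, coverage 29.5 reads), and the kinase gene Map3k13 had 49.3% ± 13.7 against 25.9% ± 13.1 (chromosome 16, 21896401 to 21896500, coverage 118 reads). The scavenger receptor gene Stab1 had 60.4% ± 9.19 against 40.4% ± 9.50 (chromosome 14, 31138501 to 31138600). The gain of 18.2 points counted for its neighbour Nt5dc2 was at 31138701 to 31138800, also a tile of Stab1, so these genes do not stand for separate regions. Other gains were those of the pancreatic carboxypeptidase gene Cpa1 (23.0 points), the nuclear pore gene Nup93 (19.8), Rgl1 (19.7) and the lysosomal gene Psap (18.1). Sec14l5 (17.6), D6Ertd527e (17.2), Enc1 (16.1) and the DNA polymerase gene Pold1 (15.8) followed. None of these 12 tiles had an adjusted p under 0.05 on HFD. Of the 12 calls, 10 were lost in at least 1 of the 24 fits without 1 male. They were lost in 7 such fits for Sec14l5, 6 each for Nup93 and Enc1, 3 each for Cpa1 and Psap and 1 each for the others. The library whose absence gave the highest adjusted p is named for each. Without Het on MCD 4 the adjusted p was 0.0512 for Ptprm, 0.0829 for Cpa1 and 0.0956 for Pold1. Without WT on MCD 4 it was 0.0542 for Map3k13 and 0.0727 for Stab1. Without Het on MCD 1 it was 0.0512 for Rgl1 and 0.103 for Enc1. It was 0.183 for Nup93 without Het on MCD 2, 0.0646 for Psap without WT on MCD 3 and 0.0938 for Sec14l5 without WT on MCD 6. By edgeR the adjusted p was 0.0708 for Nup93, 0.117 for Enc1 and 0.0581 for Pold1.

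In the windows searched for imprinted regions methylated in sperm, 3 of 4 tiles lost methylation in Het males on MCD. In the window searched for the paternally methylated control region upstream of Rasgrf1 (chromosome 9, 89878001 to 89878100, 2 CpGs, coverage 211.5 reads), the level was 66.1% ± 7.84 in Het and 86.2% ± 2.89 in WT males (adjusted p = 1.12e-05, 6 of 6). In the window upstream of Zdbf2 (chromosome 1, 63183901 to 63184000, 2 CpGs, coverage 80 reads), it was 73.6% ± 6.49 against 93.3% ± 4.70 (adjusted p = 5.11e-05, 6 of 6). This window was counted from the first base of the gene record, 63200358, and may miss the paternally methylated region of Zdbf2. The tile upstream of Meg3 (chromosome 12, 109528801 to 109528900, coverage 118 reads) had 97.6% ± 2.34 against 97.9% ± 1.64 (adjusted p = 0.936), and none was measured near H19. Over the 4 tiles the mean was 77.3% ± 5.96 against 91.7% ± 1.69, a difference of -14.3 points (exact p = 0.00216, adjusted p = 0.00758, 6 of 6). Of the 4 tiles, 3 were called, as they were adjusted over the list alone. Imprinted regions methylated in oocytes stayed near 0 in both genotypes: 65 tiles of 12 genes such as Peg3, Mest and Nnat averaged 0.499% ± 0.175 in Het and 0.409% ± 0.230 in WT males (exact p = 0.459).

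**Figure D2:**
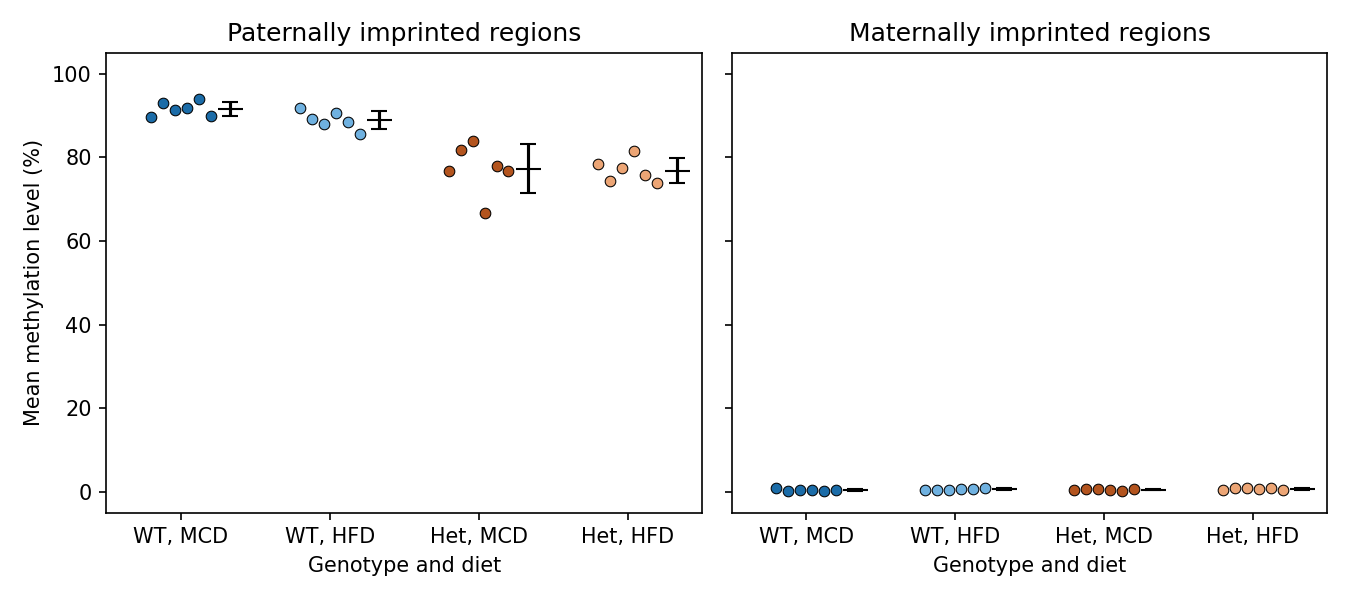
Mean methylation level in percent (y axis) of imprinted regions in the 4 groups of genotype and diet (x axis). Tiles in the windows searched for paternally methylated regions (4 tiles) are on the left and oocyte-methylated regions (65 tiles) on the right. Each point is 1 male, and bars give the mean and SD (n = 6). The tiles on the left averaged 91.7% in WT and 77.3% in Het males on MCD, and 89.0 and 76.9% on HFD.

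Clustered protocadherins, olfactory and vomeronasal receptors and zinc finger genes were lower in Het males on MCD near their CpG-dense ends, as were CpG-dense ends of all genes (-0.268 points, exact p = 0.00216, with 2.72% of tested tiles lower). The lists were not tested against other genes. Clustered protocadherins, which give neurons their surface identity, averaged 4.75% ± 0.180 against 5.40% ± 0.101 over 41 of 57 genes (exact p = 0.00216, adjusted p = 0.00758, 6 of 6 Het males below the WT mean). Of 42 tested tiles, 6 were lower, as when adjusted over the list alone, in Pcdhb13 (-24.2 points, 35.8% ± 8.52 against 60.0% ± 8.34, chromosome 18, 37442801 to 37442900), Pcdhga10 (-11.9) and Pcdhga4 (-10.0). Olfactory and vomeronasal receptors averaged 40.8% ± 0.603 against 43.0% ± 0.403 over 59 genes (adjusted p = 0.00758, 6 of 6). Of their 103 tiles, 6 were lower, or 7 adjusted over the list alone. Among them, the pheromone receptor gene Vmn2r29 had 35.6% ± 4.01 against 52.1% ± 5.50 (chromosome 7, 7278101 to 7278200, 14 CpGs, coverage 1227 reads, adjusted p = 1.93e-06), Vmn1r213 -19.2 points, Olfr323 -15.4 and Olfr976 -13.9. Zinc finger genes averaged 4.09% ± 0.0567 against 4.34% ± 0.0545 over 314 of 403 genes (adjusted p = 0.00758, 6 of 6). Of their 198 tiles, 10 were lower, as when adjusted over the list alone. They lay in Zfp229 (22.3% ± 7.25 against 51.2% ± 9.40, chromosome 17, 21730401 to 21730500), Zfp655 (-13.9 points) and Zfp536 (-12.4). With a library left out, the adjusted p was 0.0548 for Olfr323 (Het on MCD 4), 0.130 for Olfr976 (Het on MCD 6) and 0.152 for Zfp655 (WT on MCD 4), and the difference at Pcdhga4 was -8.84 points (Het on MCD 1). By edgeR the adjusted p was 0.0633 for Olfr323, 0.138 for Olfr976 and 0.126 for Zfp655.

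DNA methylation and piRNA genes on MCD averaged 9.11% ± 0.204 against 9.51% ± 0.206 (adjusted p = 0.0253, 6 of 6), with 1 of 20 tiles lower, at Dnmt3l itself (-10.1 points, chromosome 10, 78042601 to 78042700, adjusted p = 0.00660, and 0.0698 by edgeR). Embryo patterning genes averaged 3.79% ± 0.0832 against 3.95% ± 0.0631 (adjusted p = 0.0182, 6 of 6), with 1 of 17 tiles lower, at the heart transcription factor gene Gata4 (-11.6 points). Among 21 germ-cell genes the mean difference was -0.0167 points (exact p = 0.898), and 2 of 29 tiles were lower, both of Fkbp6, a gene of meiosis and piRNA (49.0% ± 5.22 against 60.0% ± 4.71). Metabolic genes differed by -0.0716 points (adjusted p = 0.0519, 6 of 6), Hox genes by -0.0399 (0.418) and placental genes by -0.0790 (0.634). Pluripotency genes differed by -0.171 points (adjusted p = 0.313) and epididymal epithelium markers by -0.955 (0.0909). None of these 5 lists had a called tile at a CpG-dense end. Leukocyte markers differed by 0.170 points (adjusted p = 0.591). Over whole gene bodies with 1 kb around the gene ends, metabolic genes differed by -0.267 points, Hox genes by -0.335 and placental genes by -0.575. Leukocyte markers then differed by -1.41 and the genes of the oocyte-methylated list by -1.18 (adjusted p = 0.00303 for each of the 5). The last value covers whole genes and not the imprinted regions alone. Without Het on MCD 4 the adjusted p of the methylation and piRNA list was 0.0505. That of the metabolic list was 0.0202 without WT on MCD 6, and that of the epididymal list 0.0390 without WT on MCD 2. For single tiles it was 0.0565 for Gata4 without Het on MCD 3. The difference of Dnmt3l was -9.14 points without Het on MCD 4, that of Fkbp6 -9.69 without WT on MCD 4.

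Outside genes the loss was larger than within them. Intergenic tiles averaged 66.6% ± 0.364 in Het and 69.3% ± 0.154 in WT males on MCD (-2.73 points). Gene bodies differed by -0.670 points, CpG-dense gene ends by -0.268 and the other gene ends by -0.616. Each of these had an exact p of 0.00216, an adjusted p of 0.00242 and 6 of 6 Het males below the WT mean. Lower tiles made up 7.14% of tested intergenic tiles, 1.79% of those in gene bodies and 2.72% of those at CpG-dense ends. Grouped by their mean level over all males, Het included, tiles of intermediate level differed most: the difference was -7.23 points for tiles with a mean level of 40 to 60% and -7.02 for 60 to 80%, against -1.05 for 2 to 20% and -0.436 for 90 to 98%. A tile with a large loss cannot average 90% or more over all males. Grouped by the WT males on HFD, a choice made after seeing the data, the differences were -6.69, -7.04, -0.846 and -0.708 points for the same 4 groups (exact p = 0.00216 each). Tiles below 2% differed by 0.0218 points (exact p = 0.162) and those above 98% by -0.0400 (exact p = 0.418). By chromosome, 3.74% of autosomal tiles were lower, 7.89% of those on X and 9.77% of those on Y. Among autosomes the share was highest on chromosome 3 at 6.14% and lowest on chromosome 11 at 1.91%.

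**Figure D3:**
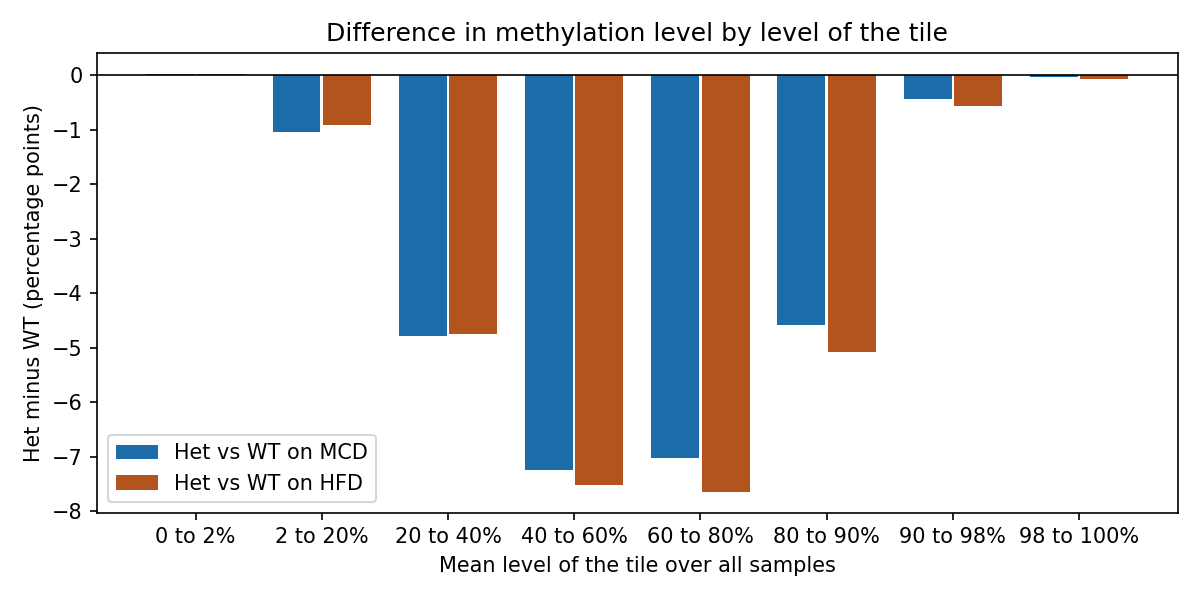
Difference in methylation level, Het minus WT, in percentage points (y axis) for tiles grouped by their mean level over all males in percent (x axis). Bars give the difference of group means (6 against 6 males) on MCD and HFD; it was -7.23 and -7.52 points for tiles of 40 to 60%, and -0.436 and -0.563 for tiles of 90 to 98%.

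**Figure D4:**
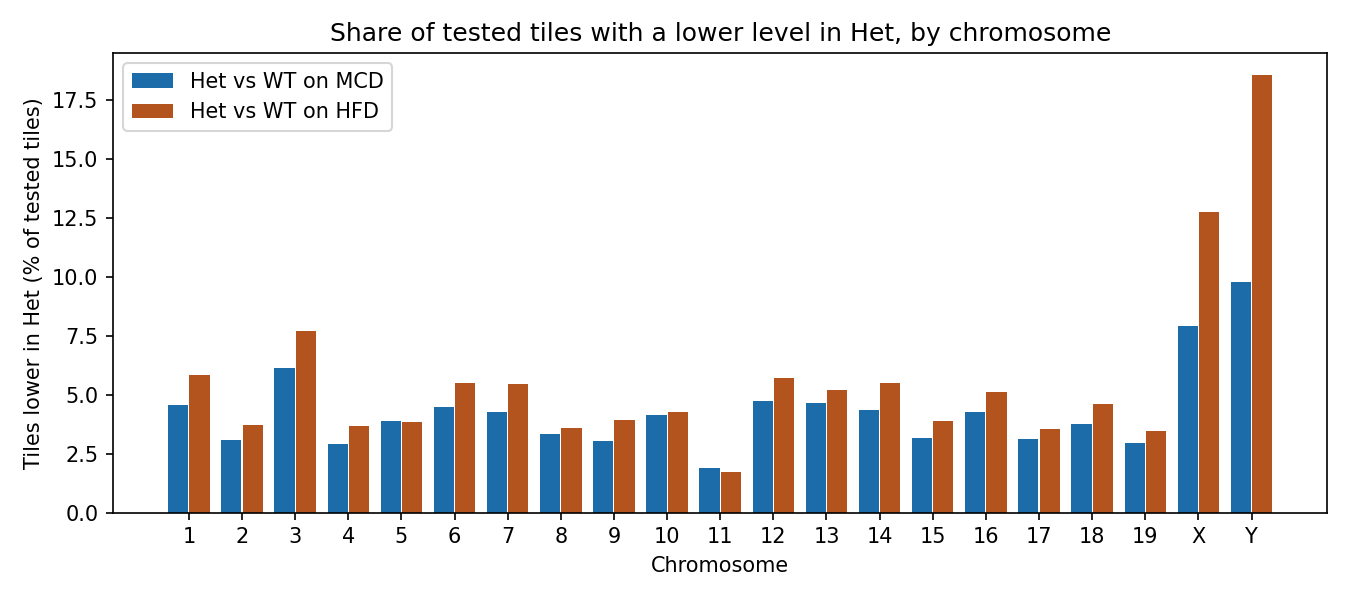
Tiles called lower in Het males as a percent of tested tiles (y axis) on each chromosome (x axis), with 1 bar for MCD and 1 for HFD. X had 7.89% on MCD and 12.7% on HFD, and Y had 9.77 and 18.5%.

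Libraries also stood apart in other measures. Reads on chromosome Y followed genotype, while methylated mitochondrial reads set apart only some of the WT libraries. On chromosome Y, 190 CpGs between 37906995 and 78013618 had at least 10 reads in every WT library and none in any Het library. Methylated reads mapped to the mitochondrial genome also stood apart. In 8 WT libraries, 4 per diet, there were 0.938 to 1.36 methylated reads per M reads, against at most 0.0563 in Het libraries and 0.0314 in the other 4 WT libraries. Without these 8 libraries, 5702 tiles were called on MCD, 5660 of them lower, and 7438 on HFD, 7401 of them lower. The mean over tiles then differed by -1.15 points on MCD and -1.32 on HFD (exact p = 0.0357 each, the smallest possible with 2 WT males against 6 Het males).

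On HFD, Het sperm had again lost methylation relative to WT sperm: 14436 tiles were lower and 29 higher, and 99.8% of the called tiles were lower, with a median difference of -13.6 points. This comparison addresses the effect of Dnmt3L haploinsufficiency in males on the fat-rich diet, which again cannot be told apart from a separate breeding line. The cilium gene Cfap53 had a WT level of 64.1% ± 10.1 and a difference of -40.1 points (chromosome 18, 74295001 to 74295100, 5 CpGs, coverage 589 reads, adjusted p = 5.73e-09, lower in 6 of 6). Fto had 28.3% ± 8.42 against 67.2% ± 9.74 at the tile lowered on MCD (adjusted p = 4.67e-08, 6 of 6). Ttll7 had -38.5 points and the chromatin reader gene Brd3 -37.1 (adjusted p = 2.68e-09, 6 of 6). The sialyltransferase gene St6galnac3 had -36.9 points (6 of 6), with an adjusted p of 0.0183, and of 0.0591 without Het on HFD 5. Among named genes, the largest gains were at Rtkn2 (22.8 points, 58.9% ± 10.2 against 36.1% ± 9.87, chromosome 10, 68041801 to 68041900, adjusted p = 5.77e-05) and the chromatin remodeller gene Smarcc2 (58.0% ± 1.76 against 37.9% ± 9.16). The matrix gene Ltbp2 gained 18.7 points, Ergic1 15.4 and the clock gene Per1 14.2, and all 5 tiles were above the WT mean in 6 of 6 Het males. The adjusted p was 0.0784 for Smarcc2 without WT on HFD 4, 0.120 for Ergic1 without Het on HFD 6 and 0.0626 for Per1 without WT on HFD 5. EdgeR called neither Smarcc2, which missed the threshold narrowly (adjusted p = 0.0500015), nor Ergic1 (adjusted p = 0.0876). None of these 5 tiles had an adjusted p under 0.05 on MCD. There the differences were 13.0 points at Rtkn2, 5.63 at Smarcc2 and 4.11 at Ltbp2, but -7.99 at Ergic1 and -4.00 at Per1. Over all tiles the mean on HFD was 55.3% ± 0.246 in Het and 56.6% ± 0.144 in WT males (-1.28 points, exact p = 0.00216, adjusted p = 0.00361, 6 of 6), and -0.981 points (exact p = 0.405) weighted by each library's coverage.

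Most of the gene groups lower on MCD were lower on HFD too, as were all CpG-dense ends (-0.262 points, exact p = 0.00433, with 2.79% of tested tiles lower). Tiles in the windows searched for paternally methylated regions averaged 76.9% ± 2.87 against 89.0% ± 2.16 (exact p = 0.00216, adjusted p = 0.0101, 6 of 6), with 3 of 4 tiles lower, as when adjusted over the list alone. The tile upstream of Meg3 was not called (96.8% ± 2.90 against 99.0% ± 1.24, adjusted p = 0.368). Rasgrf1 had 65.8% ± 6.54 against 87.5% ± 4.19, and Zdbf2 had 70.9% ± 8.64 against 83.5% ± 7.04 (chromosome 1, 63183601 to 63183700, adjusted p = 0.0209, 0.0678 by edgeR and 0.0709 without WT on HFD 1). Protocadherins averaged 4.92% ± 0.245 against 5.64% ± 0.230 (adjusted p = 0.0121, 6 of 6), with 5 of 42 tiles, as when adjusted over the list alone. The differences were -26.2 points at Pcdhb13 and -13.8 at Pcdhga10. Olfactory and vomeronasal receptors averaged 40.4% ± 0.476 against 43.3% ± 0.420 (adjusted p = 0.0101, 6 of 6), with 10 of 103 tiles, or 11 adjusted over the list alone. The differences were -18.8 points at Vmn1r115, -18.0 at Vmn2r29, -17.9 at Olfr976 and -17.6 at Vmn2r104. Zinc finger genes averaged 4.09% ± 0.0521 against 4.35% ± 0.0732 (adjusted p = 0.0101, 6 of 6), with 14 of 198 tiles, as when adjusted over the list alone. The differences were -31.2 points at Zfp229, -17.2 at Zfp93 (adjusted p = 0.0861 without WT on HFD 5), -16.7 at Zfp101 (adjusted p = 0.0509 by edgeR) and -13.5 at Zfp446. Embryo patterning genes differed by -0.138 points (adjusted p = 0.0121, 6 of 6). Fkbp6 had 44.6% ± 5.32 against 61.2% ± 3.60 with 4 of 29 germ-cell tiles lower, while the germ-cell mean differed by -0.176 points (adjusted p = 0.776).

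Near CpG-dense ends, the remaining lists did not pass on HFD. The difference was -0.0994 points for Hox genes (adjusted p = 0.0606, and 0.0253 without WT on HFD 2). It was -0.233 for methylation and piRNA genes (adjusted p = 0.265, and 0.0417 without Het on HFD 3) and -0.0583 for metabolic genes (0.0996, and 0.0101 without Het on HFD 3). It was -0.00565 for placental genes (0.972), -0.0188 for pluripotency genes (0.944) and 0.0534 for oocyte-methylated imprinted regions (0.854). It was -0.163 for epididymal markers (0.776) and -0.0737 for leukocyte markers (0.917). Over whole gene bodies with 1 kb around the gene ends, 7 of these lists passed. The differences were then -0.390 points for Hox, -0.361 for metabolic and -0.622 for placental genes and -1.01 for whole genes of the oocyte-methylated list (adjusted p = 0.00379 each). They were -0.556 for pluripotency genes (0.0220), -0.254 for methylation and piRNA genes (0.0379) and -1.45 for leukocyte markers (0.00606). Intergenic tiles differed by -2.98 points and gene bodies by -0.744 (exact p = 0.00216 each, 6 of 6), and 9.17% of intergenic and 1.87% of gene-body tiles were lower. The share of lower tiles was 12.7% on X, 18.5% on Y and 4.40% on autosomes.

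Losses were shared between the diets, whose 12 males each are separate animals. Of the 12024 tiles called on MCD, 98.7% had the same direction on HFD, where 100 relabelings of the HFD males gave 2.80 to 97.2%, and their median difference on HFD was -11.9 points. Called on both diets were 7233 tiles, 7230 lower and 3 higher, which is 60.2% of the MCD calls. Lists of these sizes drawn independently from all tested tiles would share about 559 lower tiles. That number is too low as a baseline, because calls gathered at the same levels on both diets. Of tiles with a mean level of 40 to 60%, 22.3% were lower on MCD and 25.9% on HFD, against 0.0760 and 0.0921% of those of 90 to 98%. Rasgrf1, Zdbf2, Fkbp6, Vmn2r29, Zfp229, Fto, Cfap53 and Ank3 were among the genes with an adjusted p under 0.05 at the same tile on both diets. Of the 12 genes named above for MCD losses, Auts2 (-7.70 points, adjusted p = 0.505) and Cntn6 (-22.1 points, adjusted p = 0.156) did not reach it on HFD.

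Diet left no called tile in WT males: the quasi-binomial test found 0 lower and 0 higher tiles on HFD, and edgeR 0. This comparison addresses the high-fat diet in WT males. An unadjusted p under 0.05 was found at 14915 tiles (4.83%) by the quasi-binomial test and 13113 by edgeR, and the smallest adjusted p was 0.868. The mean over tiles was 56.6% ± 0.144 on HFD and 56.5% ± 0.0893 on MCD (0.0340 points, exact p = 0.641). In the window upstream of Zdbf2 the mean of 2 tiles was 84.6% ± 4.43 on HFD and 91.3% ± 3.86 on MCD (-6.63 points, exact p = 0.0216), and both tiles had an adjusted p of 0.995. Rasgrf1 differed by 1.28 points (exact p = 0.561). The list searched for paternally methylated regions differed by -2.71 points (exact p = 0.0390, adjusted p = 0.343, 5 of 6). Protocadherins differed by 0.238 (exact p = 0.0498, adjusted p = 0.343, 5 of 6; adjusted p = 0.0303 without WT on HFD 2), and embryo patterning genes by 0.0819 (exact p = 0.0736, adjusted p = 0.343). None of the other 11 lists had an adjusted p below 0.521; among them metabolic genes differed by -0.0158 points (exact p = 0.597). Chromosome X differed by 0.293 points (exact p = 0.0455, adjusted p = 0.576, 5 of 6). Simulated losses of 20 points were called at 74% of the changed tiles and of 10 points at 20%. These rates do not cover gains or tiles of the lowest and highest levels. A logistic test without overdispersion called 837 tiles, and 1 tile was called without WT on MCD 3.

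In Het males, diet again left 0 called tiles by the quasi-binomial test and by edgeR. This comparison asks whether the diet acts in males that lack 1 copy of Dnmt3L. An unadjusted p under 0.05 was found at 16530 tiles (5.36%) and at 13245 by edgeR, and the smallest adjusted p was 0.639. The mean over tiles was 55.3% ± 0.246 on HFD and 55.4% ± 0.182 on MCD (-0.0710 points, exact p = 0.565). Rasgrf1 differed by -0.290 points (exact p = 0.942), Zdbf2 by -0.390 (exact p = 0.913) and paternally methylated regions as a list by -0.459 (exact p = 0.874). Embryo patterning genes differed by 0.0982 points (exact p = 0.0498, adjusted p = 0.606, 5 of 6), and no other list had a smaller exact p. The logistic test without overdispersion called 849 tiles, and 2 tiles were called without Het on MCD 6.

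A different response to diet in the 2 genotypes was called at 1 tile, in the body of Fryl, a homologue of a fly gene of cell shape (chromosome 5, 73081101 to 73081200, 4 CpGs, coverage 315 reads). There the level was 83.3% ± 4.16 in WT males on MCD, 90.7% ± 1.04 in WT on HFD, 89.5% ± 3.85 in Het on MCD and 81.0% ± 2.21 in Het on HFD, an interaction of -15.8 points (adjusted p = 0.0279; 6 of 6 Het males on HFD below the mean of WT males on HFD). By edgeR its adjusted p was 0.323. The call was lost in 16 of the 24 fits without 1 male, with an adjusted p of up to 0.141 (without WT on MCD 1). An unadjusted p under 0.05 was found at 15658 tiles (5.07%) and at 13423 by edgeR, which called 0. None of 15 interaction tests of the mean over tiles (-0.105 points, exact p = 0.455) and of the 14 lists passed; the smallest exact p was 0.110, for epididymal markers (adjusted p = 0.842).

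Het males on HFD, set against WT males on MCD, had 13410 lower and 62 higher tiles, with a median difference of -13.7 points. This comparison addresses both factors together, and its control males are also those of the MCD comparison, so the pair of results is not independent. Genotype cannot be told apart from a separate breeding line in it either. Among named genes, the largest loss was at Ttll7 (-43.2 points from a WT level of 76.8% ± 9.80, chromosome 3, 146924801 to 146924900, coverage 81 reads, adjusted p = 0.000207, 6 of 6). Next were Iqschfp (-41.9 points), Cldn10 (-40.6), Cfap53 (-37.4), Fto (-37.0) and Ank3 (-34.9). Mid1, a ubiquitin ligase gene on X, had 31.3% ± 8.48 against 66.1% ± 13.1 (169755001 to 169755100). The others were the muscle gene Neb (-34.0 points), Tmem267 (-33.1), Pdcd7 (-33.0), the prohormone convertase gene Pcsk2 (-32.9) and the lipid phosphatase gene Synj2 (-32.9). All 12 were below the WT mean in 6 of 6 Het males, with adjusted p up to 0.00485. The mean over tiles differed by -1.24 points (exact p = 0.00216, adjusted p = 0.00361, 6 of 6), and by -0.166 (exact p = 0.861) weighted by each library's coverage. Without the 8 WT libraries with methylated mitochondrial reads, 6921 tiles were called.

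The 12 named genes with the largest gains of this comparison had 14.5 to 24.5 points, with at least 5 of 6 Het males above the WT mean and adjusted p up to 0.0483. They lay in Ybey (57.0% ± 7.32 against 32.5% ± 9.62, chromosome 10, 76458001 to 76458100), the radial spoke gene Rsph14 (24.2 points), Map3k13 (23.8), Stab1 (19.7), Ptprm (18.3) and Rtkn2 (18.0). The tiles of Ybey, Rsph14 and Rtkn2 lie on chromosome 10 within 20 Mb of Dnmt3l. The ganglioside synthase gene St8sia1 was higher than its WT level of 4.16% ± 5.52 (adjusted p = 0.0231, 6 of 6). Others were Gse1 (17.6 points), Kank4os (17.6), the transcriptional coactivator gene Ppargc1b (15.1), Rgl1 (14.9) and the guanine nucleotide synthesis gene Impdh1 (14.5). WT males on HFD had 47.7% at the Map3k13 tile and 58.5% at that of Stab1. Against them, Het males on HFD differed by 2.05 points at Map3k13 (adjusted p = 0.895) and 1.53 at Stab1 (0.892). The same difference was 6.75 points at Ptprm (0.189), 9.11 at Rgl1 (0.430) and 22.8 at Rtkn2 (5.77e-05). Of the 12 calls, 9 were lost in at least 1 of the 24 fits without 1 male. They were lost in 16 such fits for Impdh1, 15 for Ppargc1b, 9 for Kank4os, 5 each for Gse1 and St8sia1, 3 for Rgl1 and 1 each for the others. The library whose absence gave the highest adjusted p is named for each. Without WT on MCD 4 the adjusted p was 0.128 for Rsph14, 0.0588 for Map3k13, 0.0851 for Stab1 and 0.0776 for St8sia1. It was 0.0791 for Gse1 without WT on MCD 1, 0.144 for Kank4os without WT on MCD 6 and 0.308 for Ppargc1b without WT on MCD 5, where the difference was 8.84 points. It was 0.0721 for Rgl1 without Het on HFD 3 and 0.114 for Impdh1 without Het on HFD 2. By edgeR it was 0.0590 for Stab1, 0.0826 for Gse1, 0.0735 for Kank4os, 0.107 for Ppargc1b, 0.0773 for Rgl1 and 0.0968 for Impdh1.

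Against WT males on MCD, 4 of the 14 lists passed in Het males on HFD, each lower in 6 of 6 males. All CpG-dense ends differed by -0.252 points (exact p = 0.00216), with 2.71% of tested tiles lower. Tiles in the windows searched for paternally methylated regions differed by -14.8 points (adjusted p = 0.0101), with -20.4 at Rasgrf1 and -19.4 at Zdbf2. The Meg3 tile differed by -1.01 points (adjusted p = 0.828). Protocadherins differed by -0.479 (adjusted p = 0.0152), with -21.6 at Pcdhb13 and -12.5 at Pcdhga10. Olfactory and vomeronasal receptors differed by -2.68 (adjusted p = 0.0101), with -19.5 at Vmn2r29, -18.9 at Vmn1r213, -18.2 at Olfr976 and -15.7 at Vmn2r104. Zinc finger genes differed by -0.251 (adjusted p = 0.0101), with -31.7 at Zfp229, -15.3 at Zfp93, -12.2 at Zfp446 and -11.7 at Zfp872. Fkbp6 was lower by a difference of -15.4 points, with 4 of 29 germ-cell tiles called. The tiles called, with the same counts adjusted over the list alone unless given, were 3 of 4 paternally methylated, 5 of 42 protocadherin, 11 of 103 receptor (12 adjusted over the list alone) and 13 of 198 zinc finger tiles. The protocadherin list had an adjusted p of 0.0545 at a coverage minimum of 20 reads. Oocyte-methylated regions differed by 0.250 points (adjusted p = 0.143, and 0.0424 without WT on MCD 1). Methylation and piRNA genes differed by -0.337 (0.143, and 0.0354 without Het on HFD 3) and metabolic genes by -0.0741 (0.143, and 0.0354 without Het on HFD 3). Near CpG-dense ends no pass was reached by Hox genes (-0.0713 points, adjusted p = 0.209), embryo patterning genes (-0.0557, 0.209), pluripotency genes (-0.192, 0.209) or placental genes (0.0502, 0.823). The same holds for germ-cell genes (-0.00495, 0.991) and markers of epididymis (-0.549, 0.209) and leukocytes (-0.113, 0.823). Over whole gene bodies with 1 kb around the gene ends, Hox (-0.324 points), embryo patterning (-0.453), pluripotency (-0.763) and metabolic genes (-0.307) and the genes of the oocyte-methylated list (-0.988) passed, with an adjusted p of 0.00337 each. So did placental genes (-0.566), leukocyte markers (-1.41; 0.00551 each) and methylation and piRNA genes (-0.355, 0.00758). By edgeR the adjusted p was 0.0910 for Zfp93, 0.0516 for Zfp446 and 0.0893 for Zfp872. With a library left out it was 0.151 for Zfp93 and 0.0677 for Zfp446 (WT on MCD 5) and 0.122 for Zfp872 (Het on HFD 6).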

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

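The tests on chromosome Y in this part were chosen after the result was seen. Chance alone puts a male far from its group in about 1 in 20 groups, and 20 of the 356 groups of 6 males examined had such a male, where chance gives 17.8.

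Among the gene lists, 3 means had a male far from the other 5 of its group: placental genes in WT on HFD 4 (5.88%, others 6.51 to 6.82), protocadherins in WT on HFD 2 (5.19%, others 5.61 to 5.82) and zinc finger genes in WT on HFD 3 (4.21%, others 4.33 to 4.41). Among the tiles lower in Het males, a male stood apart at Cntn6 in WT on HFD 6 (90.5%, others 49.0 to 64.3), Fto in WT on MCD 5 (52.1%, others 65.1 to 70.1), Myl10 in WT on MCD 1 (66.7%, others 77.3 to 83.3), Adgrv1 in WT on HFD 4 (63.6%, others 82.0 to 92.9) and Adam3 in WT on HFD 4 (69.5%, others 56.4 to 61.1). In the receptor, protocadherin and zinc finger families it was Pcdhb13 in Het on MCD 1 (52.0%, others 26.7 to 35.5), Olfr976 in Het on HFD 4 (62.5%, others 42.4 to 48.5), Vmn2r104 in WT on HFD 6 (79.6%, others 71.4 to 74.4), Zfp93 in WT on MCD 1 (37.8%, others 57.3 to 62.5) and Zfp655 in WT on MCD 5 (50.8%, others 70.6 to 75.0) and in WT on HFD 2 (41.0%, others 60.6 to 71.9). Among the tiles higher in Het males it was Psap in WT on MCD 3 (40%, others 62.5 to 74.1), Sec14l5 in Het on MCD 6 (80.4%, others 86.6 to 90.1), Gse1 in WT on HFD 5 (23.1%, others 38.5 to 41.9), Impdh1 in WT on MCD 2 (87.5%, others 72.0 to 75.0), Ergic1 in WT on HFD 3 (33.3%, others 59.7 to 70.0) and Per1 in WT on MCD 1 (93.3%, all others 100%).

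The Fryl tile was lower in Het than in WT males on HFD and higher in Het males on MCD, so that the genotype difference on HFD minus that on MCD was -15.8 points, by a test of this difference itself (adjusted p = 0.0279; 6 of 6 Het males on HFD below the mean of WT males on HFD). Of 100 regroupings in which diets were permuted within each genotype, the real one included, 15 called at least as many tiles as the real 1 and the highest of the others called 27, so chance was not excluded.

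Chromosome Y differed between the genotypes in what was read at all: 190 CpGs, of 4660 read at least 10 times in every WT library, had no read in any Het library, and 4 CpGs (32123214, 32260048, 90718580 and 90718610) were read at least 10 times in every Het library and in no WT library. A lower depth of the Het libraries is argued against by a mean total coverage 1.01 times that of WT libraries. Outside these CpGs, the share of reads of all Het libraries lay on 1 side of all WT libraries in 66 of 585 windows of 10 kb on Y (11.3%). In 62 of them it lay below. On X this held in 0 of 4071 windows (Fisher exact p = 1.23e-61 over windows). Windows of 1 chromosome in the same males are not independent, so this p overstates the evidence. A different structure of the Y chromosome in the line of the Het males may give such a pattern. Whether that structure came with a separate breeding line was not recorded in the labels. With tiles on Y left out, 11904 tiles were called on MCD and 14230 on HFD.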

How the results depend on the processing

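The settings without chromosome Y, without the WT libraries that stand apart, with weights common to all libraries and with level classes set by the WT males of the other diet were chosen after seeing the data; the others were planned. In the genotype comparisons, every setting run kept the loss of tiles, and the called counts on MCD, on HFD and for Het on HFD against WT on MCD moved as follows. A threshold of 20 points gave 1637, 1742 and 1768 tiles, by construction fewer than 12024, 14465 and 13472. Single CpGs gave 36652, 47742 and 42767. At least 1 CpG per tile gave 23006 on HFD and 20291 for the last comparison. Without the 8 WT libraries with methylated mitochondrial reads the counts were 5702, 7438 and 6921, where 2 WT males per diet remained. By edgeR they were 9146, 11134 and 10149, of which 9130, 11130 and 10141 were called by the quasi-binomial test too. Leaving out 1 male gave 10722 to 12374, 13161 to 15380 and 12147 to 14387. The mean over tiles differed by -1.21 to -1.12, -1.34 to -1.24 and -1.31 to -1.20 points without 1 male. Weighted by each library's own coverage it was 0.933 points on MCD (exact p = 0.468), -0.981 on HFD (0.405) and -0.166 for the last comparison (0.861); with weights common to all libraries it was -0.822, -0.905 and -0.861 (exact p = 0.00216 each), so the change came from weights that differ between libraries. Tiles of 40 to 60% on HFD differed by -6.83 points with classes set by the WT males on MCD, and by -7.52 with classes set by all males. For diet, the logistic test without overdispersion called 837 tiles in WT males and 849 in Het males. Of the 837, 49.8% had the same direction in Het males, a share with no value in the quasi-binomial test, which called 0. The logistic test takes the spread between males as 0. Without 1 male the counts were 0 to 1 in WT males (1 without WT on MCD 3) and 0 to 2 in Het males (2 without Het on MCD 6). The mean then differed by -0.000424 to 0.0771 points in WT and -0.134 to -0.0301 in Het males. The interaction gave 2405 tiles without overdispersion. It gave 0 tiles with single CpGs, a 20-point threshold, no filter on level, edgeR, without the 8 WT libraries, without the 4 WT libraries with a Y gap and without WT on MCD 2 and WT on HFD 3, and 0 to 3 without 1 male, where the count moved in 18 of 24 fits (2 without Het on HFD 3 and 3 without Het on MCD 6). With the sample number as a block, the genotype counts were 12145, 14486 and 13546, diet gave 0 and 0 and the interaction 0; males with the same number in different groups did not vary together (correlation of deviations -0.0844 to 0.0562), so numbers do not pair them. For the gene lists, whole gene bodies gave 35 of 70 tests past the threshold in place of 15, and some signs turned. Whole genes of the oocyte-methylated list had -1.18 (MCD), -1.01 (HFD) and -0.988 points (Het on HFD against WT on MCD). These values include tiles outside the imprinted regions, so they are not a loss at those regions. Leukocyte markers turned to -1.41 (MCD) and placental genes to -0.566 (Het on HFD against WT on MCD). Without 1 male 14 to 20 tests passed. The Dnmt3l coverage difference was -1.50 to 0.318 per M reads on MCD and -3.21 to -0.930 on HFD without 1 male. Of the 100 named calls, edgeR kept 79, and 64 stayed without any 1 male. Apart from the changes that follow by construction, the cause was not tested. Simulated diet losses of 10 points, at tiles of intermediate to high level only, were called at 20% of the changed tiles in WT males and 32% in Het males.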

Other observations

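The tests of body cells, of a separate breeding line and of DNA of another strain near Dnmt3l were chosen after the result was seen, as were the genes named in the first 2 paragraphs; the tests of a variant at 1 CpG of a lower or higher tile and of other groupings of the males were planned.

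Some genes held many lower tiles. Of 124 tested tiles in and around Ank3, 17 were lower on MCD and 18 on HFD, with a mean difference of -26.3 points over the lower tiles on each diet. Ank3 lies on chromosome 10 within 20 Mb of Dnmt3l, and whether lower tiles gather near Dnmt3l was not tested. On chromosome 10 as a whole, 4.13% of tested tiles were lower on MCD and 4.27% on HFD, against 3.74 and 4.40% on autosomes. All 9 tested tiles of Trim34a, an antiviral gene, were lower on both diets, by a mean of -25.0 points on MCD and -24.9 on HFD. On MCD, all 8 tiles of the axon guidance gene Flrt3, which lies within Macrod2, were lower (-20.6 points), as were 8 of 11 of the adhesion gene Pvr, 8 of 15 of the immune kinase gene Jak3, 10 of 23 of Tmem267 and 10 of 38 of the receptor kinase gene Epha2. On HFD, 15 of 23 tiles of Tmem267, 12 of 21 of Skint5 and 10 of 22 of Skint6, relatives of the epidermal T cell selection gene Skint1, 14 of 48 of the skin gene Flg2, 9 of 32 of Snhg14, the host transcript of an imprinted cluster of small RNAs, and 9 of 9 of Zfp229 were lower. The largest regions held 22 lower tiles on MCD and 25 on HFD.

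Sex chromosomes had a larger share of lower tiles than autosomes. Autosomal tiles of the same level in the WT males of the other diet and the same coverage as those on X would give 6.23% lower tiles on MCD and 7.76% on HFD, where X had 7.89 and 12.7%. For Y the same matching gives 11.2 and 13.3%, where Y had 9.77 and 18.5%. By CpG number, tiles with 2 CpGs differed by -1.34 points on MCD and those with 8 CpGs or more by -0.164 (exact p = 0.00216 each). Of the tested tiles, however, 3.31% of those with 2 CpGs and 5.54% of those with 8 or more were lower, and 2994 of the 41016 tiles with 8 or more were tested.

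Of 4 WT libraries, WT on HFD 1, 3 and 5 and WT on MCD 3, each lacked reads at the same 180 CpGs of Y. The 8 WT libraries with methylated mitochondrial-mapped reads had mean tile levels of 56.4 to 56.8%, and the other 4 WT libraries 56.4 to 56.7%.

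Het sperm had lower methylation than WT sperm on both diets. A sequence variant at 1 CpG of a tile is argued against as the whole cause, since in 96.8% of 2871 lower tiles with 2 CpGs, called on both diets, both CpGs were lower by at least 5 points. Body cells among the Het sperm are argued against too, since they would raise the imprinted regions methylated in oocytes. The larger of the differences there was 0.0899 points. The rise taken to speak for body cells was 3.45 points. It was set after the result was seen, as a fixed share of the median loss at called tiles on MCD, and was not derived from a fraction of body cells. A separate breeding line of the Het males cannot be told apart from the genotype, because the 190 CpGs on Y that only WT libraries read split the males as genotype does. A role of the missing copy of Dnmt3L is a hypothesis that stays open beside this.

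Chance was excluded for the genotype comparisons by other groupings of the same males. Of 100 groupings into 6 and 6, the real one included, 1 called as many tiles as the real one in each: 12024 on MCD with 3600 in the highest other, 14465 on HFD with 4838, and 13472 for Het males on HFD against WT males on MCD with 3171. For diet the real grouping called 0 tiles, so all 100 of 100 groupings called as many; the highest other called 1 in WT and 23 in Het males.

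Tiles with higher methylation in Het males were frequent on chromosome 10, where Dnmt3l lies. Within 20 Mb of Dnmt3l, 7 of 4116 windows of 1 kb held one (0.170%), against 68 of 157893 on the other autosomes (0.0431%), an odds ratio of 3.95 (Fisher exact p = 0.00299), in a comparison made after the excess on chromosome 10 was seen. Elsewhere on chromosome 10 the share was 0.129% (6 of 4655 windows). Against these the odds ratio was 1.32 (Fisher exact p = 0.782), so the excess was not placed near Dnmt3l, and whether DNA of another strain was kept around the targeted gene stays open. The window counts cover tiles called between Het and WT males on the same diet. They leave out the largest named gains of Het males on HFD against WT males on MCD, at Ybey and Rsph14. Both tiles lie within 20 Mb of Dnmt3l. A variant at 1 CpG is argued against as the whole cause, since 95% of the 20 higher tile calls on chromosome 10 had at least 2 CpGs higher by 5 points or more. Examples chosen after their values were seen are Rtkn2 and a region from 68068201 to 68068500 (50.6% against 29.5% on MCD and 59.3% against 31.1% on HFD in its middle tile) and Dot1l, a histone methyltransferase gene (10.6 and 11.0 points). The strain background was not in the labels.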
